A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

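Ribosome profiling, which sequences the mRNA fragments that ribosomes protect from nuclease, was used to measure translation in Saccharomyces cerevisiae strain Y7092. This haploid laboratory strain lacks several biosynthetic genes and is used for systematic genetic crosses. The 4 libraries cover 4 groups, with 1 library per group. Wild-type and vps35 deletion cells carried either pAG416GAL-ccdB, a URA3 plasmid with a galactose-inducible promoter, which served as the control, or a plasmid for TIF4631. Per the labels' protocols, cells were grown to early log phase, plasmid-borne genes were induced for 2 h, and cells were filtered, frozen and ground. Lysates were treated with RNase I, ribosomes were pelleted through sucrose, fragments of footprint size were taken from a gel, and ribosomal RNA was removed by subtraction. No matched RNA sequencing was analysed here, so the values hold mRNA level and translation together and no translational efficiency was computed.

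The deposited tables hold 2 values for each of 5441 open reading frames (ORFs). The deposited counts are whole numbers of reads per ORF, named as total reads per the file headers. The second deposited value is RPKM, which the authors scaled by ORF length and by the reads of the dataset, per the file headers. Dividing counts by RPKM gave back the length used. It was 15 nt below the annotated gene length, within 0.01 nt, for 96.0% to 96.1% of matched ORFs, and the denominator was the summed count of the same table. RPKM was used only for this check. Per the submitters' processing notes, CASAVA, cutadapt 1.3, Bowtie2 and the sacCer3 build were used. The counting tool, the ORF annotation, the treatment of reads with several matches and any filters are not given in the sources used here. Of the ORFs listed, 5438 matched a locus tag of the R64 reference, which is the same assembly as sacCer3, and 3 did not. Another 594 of the 6021 protein-coding genes of that reference were not analysed here, among them many members of duplicated families. Genes that overlap or have close copies, such as AI1 and AI2, which share exons with COX1, may carry reads of their neighbours.

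Summed counts were 17669055 in the wild-type control library, 18067205 in the library labelled wild type with TIF4631, 11240681 in the vps35 deletion control library and 16341045 in the vps35 deletion library with TIF4631. No pair of libraries agreed within sampling noise: chi-square per degree of freedom over ORFs lay between 19.55 and 244.5. The median ORF had 860, 859, 552 and 809 counts in that order. A count of 0 is compatible with up to 3 counts, which is 0.170, 0.171, 0.264 and 0.180 CPM in the same order. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only.

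ORFs with a summed count of at least 200 over the 4 libraries were kept, which left 4997 and removed 444. Scaling factors were computed by the TMM method of edgeR 4.0.16 over all 4 libraries and were 0.997, 0.971, 1.01 and 1.02. For each of 4 contrasts a log2 ratio per ORF was computed from scaled counts with 0.5 counts added, with a 95% conditional binomial interval (Clopper-Pearson). The difference between the TIF4631 effects in the 2 strains, called the interaction below, was given a 95% interval by a normal approximation on log counts. With 1 library per group there is no spread between replicates and no test of these contrasts. An ORF was called higher or lower by a rule of size, a log2 ratio of at least 1 in either direction with an interval that excluded 0. Differences described this way compare libraries, not conditions, and have no replicate check.

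The only test across samples was an additive model with strain and plasmid as factors, fitted to all 4 libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom and counts any interaction as residual spread. Its common dispersion was 0.0245, a biological coefficient of variation of 15.7%. DESeq2 1.42.0 and limma 3.58.1 in R 4.3.3 gave alternatives. Gene lists were tested in this model with camera of limma, using its preset correlation and, separately, an estimated one. For the contrasts, each of 34 gene lists, of 35 fixed beforehand, was described by its median log2 ratio and by that median's percentile among 10000 random lists of the same size matched on deciles of mean level. The list of a-cell-specific genes had no measured ORF above the filter. Correlations across genes were computed only between contrasts that share no library, and genes are not independent replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

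The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes TIF4631 and VPS35 in every library, then the 10 highest and 10 lowest ORFs past the rule of size in each contrast, ranked by the interval bound nearest 0. It also takes 2 to 4 leading members of each described list, the retromer, translation initiation and marker genes, and the 10 ORFs with the lowest adjusted p in each direction of the additive model. The alternatives were total count scaling, DESeq2 size factors, total counts without the 50 most abundant genes, no filter beyond 1 count, a filter of 1000 summed counts, a prior count of 5, and other tests for the additive model. An alternative chosen after the data were seen leaves the library labelled wild type with TIF4631 out of scaling and filtering.

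The procedure was tested on simulated data for 4997 ORFs with counting noise. For the TIF4631 contrast in vps35 deletion, 100% of the ORFs changed 3-fold, 0% of those changed 1.5-fold and 0% of unchanged ORFs passed the rule of size. With counting noise alone the cutoff nearly fixes these shares, so they give no rate of false calls between cultures. In the real contrast the robust SD of log2 ratios was 0.303, against a median counting SD of 0.075. The simulated libraries of this contrast were not scaled by TMM. Intervals held the true value for 94.85% of unchanged ORFs at the simulated depth, and for 91.99% when libraries were scaled by their summed counts, which the changed genes move. In the additive model with simulated spread on 4991 ORFs, 100% of 3-fold TIF4631 effects, 18% of 1.5-fold effects and 0.125% of unchanged ORFs had an adjusted p under 0.05. That simulation gave each changed ORF the same change in both TIF4631 libraries. It therefore does not give the power for effects seen in a single strain, and TIF4631 itself was raised only in vps35 deletion.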

Results

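Ribosome footprints were sequenced from yeast with and without VPS35, the core subunit of the retromer complex that returns membrane proteins from endosomes, and with and without a galactose-inducible plasmid for TIF4631, which encodes the translation initiation factor eIF4G1. The series asks whether the yeast counterparts of 2 Parkinson's disease genes, VPS35 and EIF4G1, act together. Each of the 4 combinations of strain and plasmid was measured in 1 library, with no replicates, and summed counts ranged from 11240681 to 18067205. Intervals printed for single genes in the contrasts are therefore 95% counting intervals, which leave out the spread between cultures, and only the additive model gives standard errors (SE). The galactose enzyme gene GAL1 held the highest count in 3 of the libraries, at 2.76%, 3.02% and 2.77% of all counts, and PDC1 led the vps35 deletion library with TIF4631 at 2.24%.

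VPS35 (YJL154C, chromosome X, 131101 to 133935, sacCer3) had 2187 counts in the wild-type control library and 1974 in the library labelled wild type with TIF4631. The deletion libraries held 9 counts with the control plasmid and 10 with the TIF4631 plasmid, log2 ratios of -7.24 (interval -8.43 to -6.37) and -7.48 (-8.62 to -6.67) to the wild-type library with the same plasmid label. TIF4631 (YGR162W, chromosome VII, 824059 to 826917) stood at 454.7 CPM in the wild-type control library and 435 CPM in the deletion control library. In the vps35 deletion library with the TIF4631 plasmid it reached 6216 CPM from 103723 counts, 14.3-fold above its control, a log2 ratio of 3.84 (3.80 to 3.88). The library labelled wild type with TIF4631 held 403 CPM, a log2 ratio of -0.17 (-0.22 to -0.13) to the wild-type control. The target gene thus went against that label, and each direction below that draws on this library describes the library labelled wild type with TIF4631, in which no excess of TIF4631 footprints was measured. TIF4632, which encodes the second eIF4G, lay between 126.8 and 162.2 CPM, and CDC33, the cap-binding eIF4E, between 416.6 and 466.2 CPM in the 4 libraries.

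**Figure D1:**
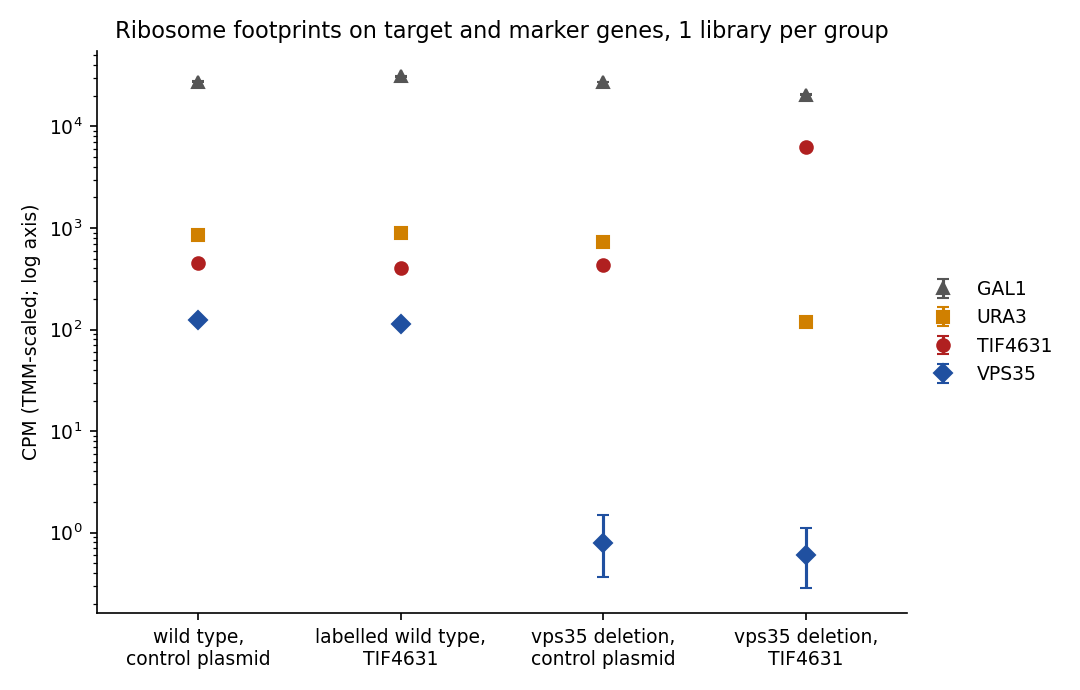
TMM-scaled CPM on a log axis for GAL1, URA3, TIF4631 and VPS35 in each of the 4 libraries, with bars for the exact 95% Poisson interval of the count, most of them smaller than the symbol. TIF4631 stands at 6216 CPM in the vps35 deletion library with TIF4631 and at 403 CPM in the library labelled wild type with TIF4631, and VPS35 is below 1 CPM in both deletion libraries.

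The plasmid and strain markers gave further checks of the labels. URA3, the selectable marker of the control plasmid, stood at 855, 884.3 and 731.7 CPM in the first 3 libraries, and at 117.9 CPM in the vps35 deletion library with TIF4631, where its log2 ratio to the deletion control was -2.63 (-2.71 to -2.56). LEU2 and MET17, which the parent strain lacks, had 0 counts in all 4 libraries, which allows at most 0.264 CPM in the shallowest. Of the other markers listed, LYP1 had 9 to 15 counts, CAN1 had 3 in the vps35 deletion library with TIF4631 and 0 elsewhere, and HIS3 had 747 to 1852, 1.69-fold higher in that library than in its control. The galactose genes, which report induction, were abundant in every library: GAL1 ranged from 20612 to 31079 CPM and GAL10 from 13403 to 23795 CPM. Both were lowest in the vps35 deletion library with TIF4631, at log2 ratios of -0.41 and -0.47 to its control.

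The contrast of vps35 deletion with wild type under the control plasmid asks what loss of retromer does alone. Genes of iron uptake were lower in the deletion library. The siderophore transporter ARN1 had a log2 ratio of -2.11 (-2.51 to -1.74), the cell wall mannoprotein FIT3 -1.76 (-1.97 to -1.56), the mRNA-decay factor TIS11 -1.85 and the multicopper oxidase FET3 -1.36. Of the 22 measured members of the Aft1/Aft2 iron regulon, 7 were lower and 0 higher by the rule of size, and the list median of -0.39 lay at percentile 0 of its random lists. The zinc transporter ZRT1 was 5.79-fold lower, at a log2 ratio of -2.53 (-2.62 to -2.45). Several mitochondrially encoded ORFs were also lower, among them AI2 at -3.18, AI1 at -2.86, OLI1 at -2.76 and COX2 at -2.06, all from few counts, so that the interval of OLI1 spanned -3.90 to -1.87. MTC7, at -2.39, and DMO1, at -2.18, completed the 10 lowest by interval bound with VPS35.

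Genes higher in the deletion control library included the transketolase TKL2 at a log2 ratio of 1.43 (1.25 to 1.61), the small heat shock protein HSP12 at 1.26 (1.20 to 1.32), the cell wall mannoprotein CWP1 at 1.22, the cell wall integrity target PRM5 at 1.31, SRL3 at 1.41 and the phosphate transporter PHO89 at 1.22. YPL088W, SIP18, YJL107C and FMP16 lay between 1.01 and 1.51. Targets of the stress factors Msn2 and Msn4 had a median of 0.24, at percentile 100, with 22 of 28 members above 0 beyond counting error and only HSP12 past the rule of size. Cell wall genes had a median of 0.14, led by CWP1, SLT2 at 0.90 and GSC2 at 0.76, and sterol biosynthesis genes one of 0.17, led by ERG6 at 0.37. Sulfur assimilation genes had a median of -0.24, at percentile 0, with the sulfate transporter SUL2 at -1.17 and MET16 at -0.65. The nuclear respiratory chain list stood at -0.10 and phospholipid synthesis at -0.18, led by INO1 at -0.72. By its locus name INO1 (YJL153C) lies next to the deleted VPS35 (YJL154C). Whether the deletion acted locally on INO1 was not tested, here or in the contrast under the TIF4631 plasmid. The other retromer subunits PEP8, VPS29, VPS5 and VPS17 lay between -0.15 and 0.16, and the list of endosome and vacuolar protein sorting genes had a median of 0.01, at percentile 65.3.

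In all, 13 of 4997 ORFs were higher and 27 lower in this contrast, and 858 were above and 864 below 0 beyond counting error alone. The counts became 24 and 47 with no filter, and 8 and 13 with a filter of 1000 counts. The robust SD of all log2 ratios was 0.148, against a median counting SD of 0.074.

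The TIF4631 contrast in wild type was meant to give the effect of the factor with retromer intact, but rests on the library labelled wild type with TIF4631. Genes of biotin uptake and synthesis were among the higher ORFs. The transporter BIO5 was 52.2-fold higher, at a log2 ratio of 5.71 (5.45 to 5.99), and the biosynthetic genes BIO3, BIO4 and BIO2 followed at 4.52, 4.29 and 2.55, with the biotin importer VHT1 at 2.39 (2.34 to 2.44). ZPS1, a zinc-responsive gene, stood at 4.43, YJR154W at 4.20, YPR108W-A at 1.76, EGO4 at 1.296 and INO1, which encodes inositol phosphate synthase, at 1.68 (1.67 to 1.69). The 5 lower ORFs were the phosphate transporter PHO84 at -1.44 (-1.61 to -1.28), the ammonium exporter ATO3 at -1.39, INA1 at -1.13, MTC7 at -1.12 and JJJ3 at -1.01.

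Some lists of translation genes had medians below their random lists in that library, with 0 members past the rule of size, but elongation and termination factors, with a median of -0.13, and tRNA synthetases, with -0.09, lay inside their random lists. Ribosome biogenesis genes had a median of -0.36, with 61 of 62 members below 0 beyond counting error, and DBP2 at -0.90 and NSR1 at -0.75 leading. Cytosolic ribosomal protein genes stood at -0.25, with 67 of 67 measured members lower beyond counting error, although the list names 138 genes. Initiation factors stood at -0.18, led by SUI3 at -0.32 and NIP1 at -0.29. The medians of these 3 lists were at percentile 0. Msn2/Msn4 targets had a median of 0.53 at percentile 100, with the catalase CTT1 at 1.07, GPH1 at 0.78 and PGM2 at 0.70. Vacuolar hydrolases at 0.25, autophagy genes at 0.20 and phospholipid synthesis genes at 0.28 were each above percentile 99. A total of 23 ORFs were higher and 5 lower, which became 37 and 20 with no filter, and 3 lower with a filter of 1000 counts.

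The TIF4631 contrast in vps35 deletion cells compares 1 library with raised TIF4631 with 1 control library, both without VPS35. After TIF4631 itself, the glycine cleavage gene GCV1 was highest, at a log2 ratio of 3.53 (3.37 to 3.69), with the serine and threonine deaminase CHA1 at 2.95 (2.24 to 3.82), GCV2 at 2.78 (2.66 to 2.91) and the serine hydroxymethyltransferase SHM2 at 1.84 (1.79 to 1.89). FIT3 stood at 2.36, HSP12 at 2.07, the agglutinin subunit AGA1 at 2.08, YDR222W at 2.23 and the exporter AQR1 at 2.36. URA3 and the biotin genes were among the lowest, with BIO3 at -2.66, URA3 and BIO2 at -2.63, BIO5 at -2.40 and BIO4 at -1.81 and by VHT1 at -1.79. The nitric oxide dioxygenase YHB1 was 2.84-fold lower at -1.51 (-1.54 to -1.47), YJR154W lay at -2.04, INO1 at -1.31 (-1.34 to -1.29) and PHO89 at -1.51.

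**Figure D2:**
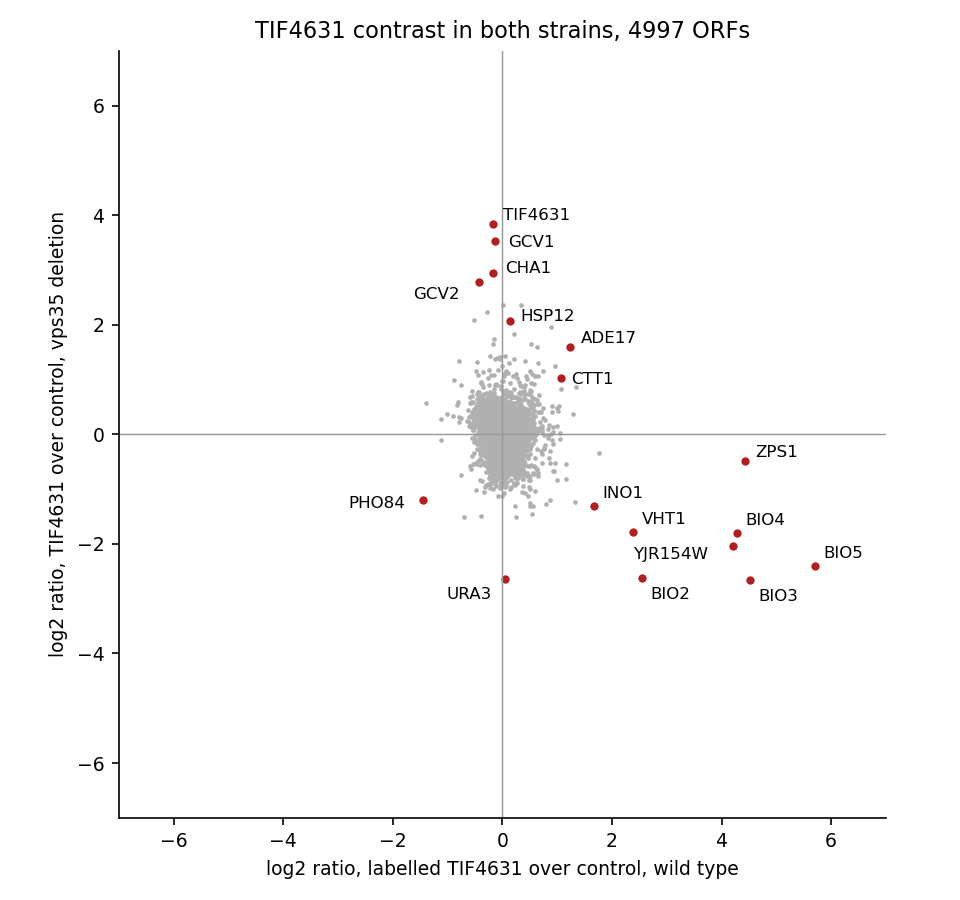
Log2 ratios of the TIF4631 contrast for 4997 ORFs, in wild type (x axis, from the library labelled wild type with TIF4631) and in vps35 deletion (y axis), with each point an ORF and red points named. TIF4631 sits at -0.17 and 3.84, and the biotin genes BIO2, BIO3, BIO4, BIO5 and VHT1 lie at the lower right, positive on the x axis and negative on the y axis.

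Sulfur assimilation genes had a median of -0.66 in this contrast, at percentile 0, with 23 of 25 members below 0 beyond counting error. Only 1 member, the S-adenosylmethionine synthetase SAM2, was past the rule of size at -1.19, and MET6 stood at -0.76. Mitochondrial ribosomal proteins had a median of -0.41, with 68 of 70 lower beyond counting error and MRP7 at -0.92, and the tricarboxylic acid cycle list stood at -0.44, with CIT1 at -0.64 and, against the median, MDH2 at 0.93. Phospholipid synthesis genes had a median of -0.47, with INO1 and the inositol transporter ITR1, at -1.04, past the rule of size. Galactose genes stood at -0.44 and sterol genes at -0.23. Ribosome biogenesis genes had a median of 0.28, at percentile 100, although NSR1 lay at -0.74, and cytosolic ribosomal protein genes 0.12. Msn2/Msn4 targets stood at 0.48, with 7 of 28 past the rule of size, among them HSP12, DDR2 at 1.59 and PHM7 at 1.38. Gcn4 targets had a median of 0.21, with HIS1 at 0.93, and haploid mating genes one of 0.32, led by SST2 at 1.32. Among initiation factors other than TIF4631, the poly(A)-binding protein PAB1 stood at -0.75 and RLI1 at 0.49, and the list median was -0.02 at percentile 56.9. The contrast held 53 higher and 28 lower ORFs, with 33 higher under a filter of 1000 counts.

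Under the TIF4631 plasmid, vps35 deletion was compared with the library labelled wild type with TIF4631, so this contrast sets a library with raised TIF4631 against a library without it. It held 79 higher and 120 lower ORFs, or 97 and 105 with total count scaling. TIF4631 at 3.95, GCV1 at 4.03, GCV2 at 3.95, AQR1 at 3.69, HSP12 at 3.19, the carbonic anhydrase NCE103 at 2.54, PRM5 at 2.51, TKL2 at 2.35, AGA1 at 2.18 and PHM7 at 2.09 were the highest by the interval bound nearest 0. BIO5 at -8.21, VPS35, BIO3 at -7.32, BIO4 at -5.95, YJR154W at -5.95, ZPS1 at -5.59, BIO2 at -4.91, ZRT1 at -4.24, VHT1 at -4.16 and INO1 at -3.71 were the lowest by that bound. Of 25 sulfur genes 10 were lower, with a median of -0.94, and of 14 phospholipid genes 6 were lower, with a median of -0.89. Of 22 iron regulon genes 5 were lower, with a median of -0.55, and FTR1 at -1.83 and ARN1 at -1.98 led them. Ribosome biogenesis genes stood at 0.53 and cytosolic ribosomal protein genes at 0.31.

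**Figure D3:**
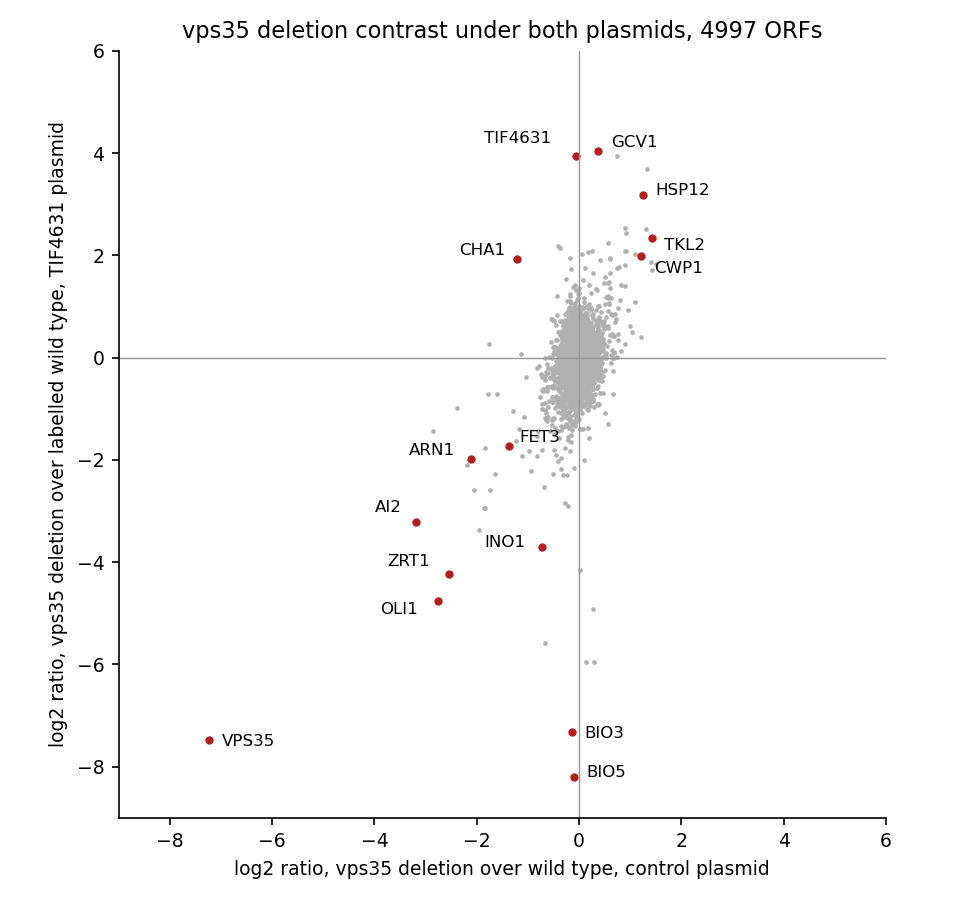
Log2 ratios of vps35 deletion over wild type for 4997 ORFs under the control plasmid (x axis) and under the TIF4631 plasmid (y axis, against the library labelled wild type with TIF4631), with each point an ORF and red points named. VPS35 lies at -7.24 and -7.48, ZRT1 and ARN1 are negative on both axes, HSP12 and TKL2 are positive on both, and BIO5 is at -8.21 on the y axis alone.

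The interaction, the TIF4631 effect in vps35 deletion minus that in wild type, was meant to ask whether the 2 genes act together. It was 79 ORFs higher and 89 lower by the rule of size, with no test, and it takes its wild-type side from the library labelled wild type with TIF4631. TIF4631 was not raised in that library, so the values below describe a difference between libraries and cannot answer that question. TIF4631 at 4.01 (3.95 to 4.07), GCV1 at 3.65, GCV2 at 3.20, CHA1 at 3.13, AGA1 at 2.59, YDR222W at 2.51, FIT3 at 2.02, ATO3 at 1.95, HSP12 at 1.93 and SST2 at 1.79 were the highest by the interval bound nearest 0. The lowest were BIO5 at -8.11 (-8.88 to -7.34), BIO3 at -7.18, YJR154W at -6.25, BIO4 at -6.10, BIO2 at -5.18, ZPS1 at -4.92, VHT1 at -4.18, INO1 at -2.99, URA3 at -2.68 and YEL073C at -2.57. Ribosome biogenesis genes had a median interaction of 0.63, with 58 of 62 above 0 beyond counting error, and sulfur genes one of -0.59, with 5 of 25 past the rule of size. Phospholipid genes stood at -0.70, with 4 of 14 past the rule. With a filter of 1000 counts, 52 ORFs were higher and 59 lower, and with total count scaling 92 were higher and 74 lower, so the balance depends on scaling.

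Across genes, the TIF4631 log2 ratios in wild type and in vps35 deletion, which share no library, had a Pearson r of -0.157 and a Spearman rho of -0.072. Of 28 and 81 ORFs past the rule of size, 3 passed in both in the same direction: ADE17 and CTT1 were higher and PHO84 was lower. Another 8 passed in opposite directions, BIO2, BIO3, BIO4, BIO5, VHT1, INO1, YJR154W and YEL073C. With no filter the Pearson r was -0.048. For the vps35 deletion ratios under the 2 plasmids, which also share no library, Pearson r was 0.411, 0.375 without VPS35 and TIF4631, and Spearman rho was 0.142. There, 10 ORFs were higher and 20 lower under both plasmids, where independent lists of those sizes would share 0.206 and 0.648. The 10 were AQR1, CWP1, HSP12, PCK1, PRM5, SIP18, SRL3, TKL2, YJL107C and YPL088W. The 20 included VPS35, the zinc genes ZRT1 and ZAP1, the iron genes ARN1, ENB1, FET3 and TIS11, SUL2, and the mitochondrially encoded ORFs AI1, AI2, ATP6, COX2, COX3 and OLI1. CHA1 passed in opposite directions.

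In the additive model over all 4 libraries, 30 ORFs passed an adjusted p of 0.05 for vps35 deletion by edgeR, 10 that rose and 20 that fell. Of the 2 library pairs behind this effect, that under the TIF4631 plasmid also differs in TIF4631, raised only in the deletion library. Strain and raised TIF4631 are confounded in that pair. After VPS35, at a log2 change of -7.42 (SE 0.225, edgeR adjusted p = 9.00e-07), AI2 fell by 3.22 (SE 0.284, adjusted p = 0.00398) and ARN1 fell by 2.04 (SE 0.204, adjusted p = 0.00649). HSP30, COX2, TIS11, ZRT1, FET3, ATP6 and COX3 also fell, with edgeR adjusted p between 0.00649 and 0.0116. TKL2 rose by 1.90 (SE 0.221, edgeR adjusted p = 0.00882), and SRL3, CWP1, PRM5, YPL088W, SIP18, YJL107C, ARO10, PHM7 and the cell wall integrity kinase SLT2 rose with adjusted p up to 0.0428. Of the 22 iron regulon genes, 4 passed over all genes and 10 adjusted over the list alone. The counts were 1 and 12 for 25 sulfur genes, 0 and 7 for 14 phospholipid genes, 1 and 10 for 28 Msn2/Msn4 targets and 2 and 5 for 28 cell wall genes. By camera with its preset correlation the iron regulon and the sulfur list fell, each with an adjusted p of 5.58e-15. With an estimated correlation no list passed by camera, and the iron regulon had an adjusted p = 0.997. That estimate rests on 1 residual degree of freedom, which leaves little power. The preset correlation is not taken from these data, so neither version settles the lists. Scaling by total counts gave 42 that rose and 41 that fell, DESeq2 size factors 19 and 28, total counts without the 50 most abundant genes 23 and 29, and the DESeq2 test 30 and 36.

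No ORF passed for TIF4631 by edgeR, with 167 at an unadjusted p under 0.05, and 0 passed by limma. DESeq2 called 6, with 2325 adjusted p-values not given. PHO84, at a log2 change of -1.32 (SE 0.153), had an edgeR adjusted p = 0.0713, and ADE17, at 1.41 (SE 0.180), an edgeR adjusted p = 0.0774. The Msn2/Msn4 targets had 0 members past over all genes and 12 adjusted over the list alone. With camera's preset correlation this list was the top call for TIF4631, at an adjusted p of 4.56e-23. With an estimated correlation no list passed by camera, and the adjusted p of this list was 0.944. The limits given above for both versions of camera hold here too. The model takes the library labelled wild type with TIF4631 as a TIF4631 library, although TIF4631 was not raised in it.

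**Figure D4:**
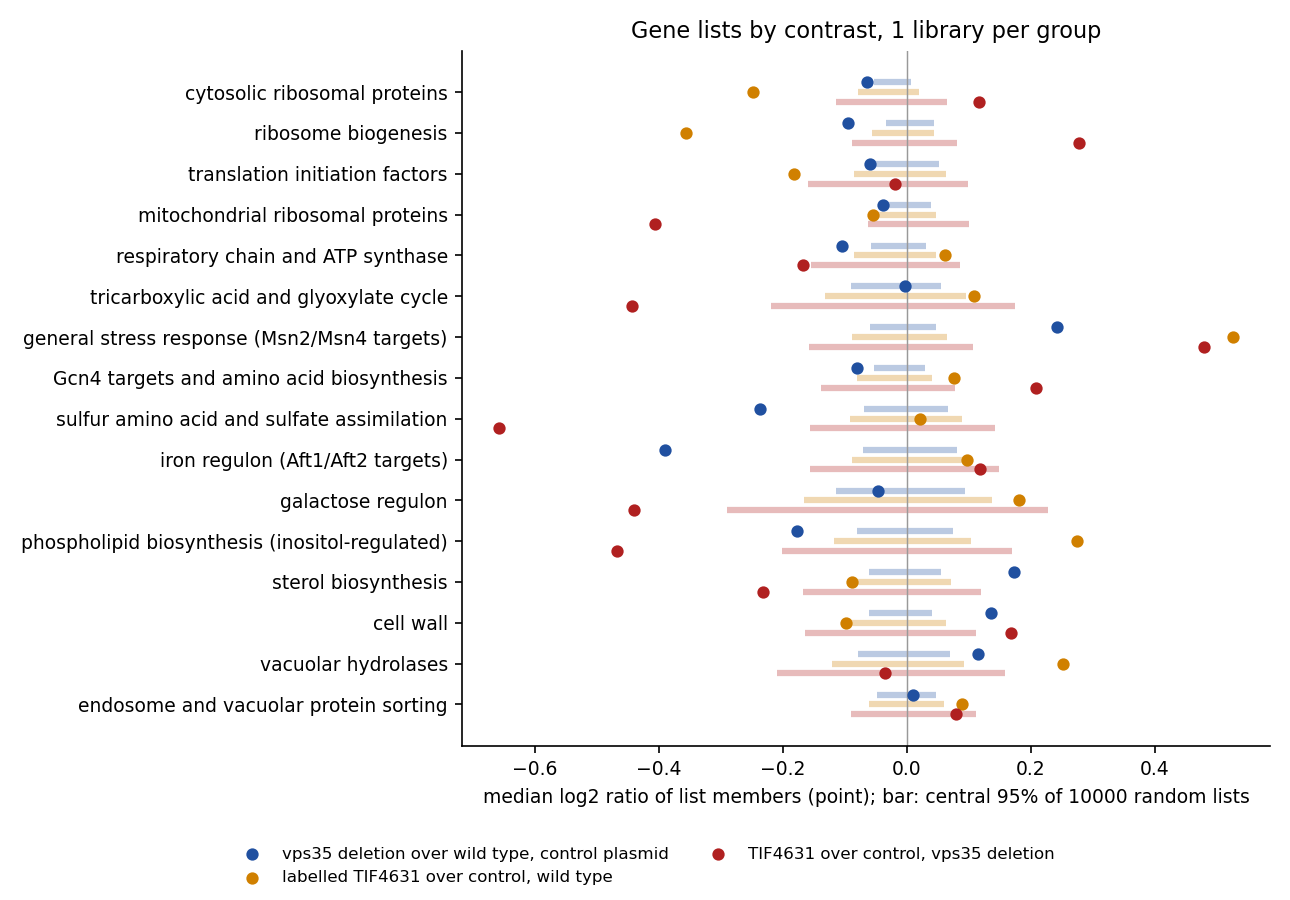
Median log2 ratio of 16 gene lists (points, x axis) in 3 contrasts with 1 library per group, with bars for the central 95% of 10000 random lists matched on mean level. Ribosome biogenesis stands at -0.36 in the contrast with the library labelled wild type with TIF4631 and at 0.28 in vps35 deletion, and the iron regulon at -0.39 in the control plasmid contrast.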

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

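All tests in this part except the values of the interaction itself were chosen after the results were seen. Apart from the mitochondrially encoded ORFs, each result here is a contrast that went in opposite directions in 2 backgrounds. There is 1 library on each side, so the differences themselves were not tested beyond counting error.

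TIF4631 differed between strains by 4.01 on the log2 scale, from -0.17 in the library labelled wild type with TIF4631 to 3.84 in vps35 deletion. A swap of plasmid labels between the wild-type libraries is argued against, since TIF4631 in the wild-type control library was 1.045 times its level in the deletion control library and so not raised there either. Absent induction is argued against by the galactose genes, whose median log2 ratio in the library labelled wild type with TIF4631 was 0.181. URA3 at 0.049 argues only against loss of a plasmid that carries URA3, and does not show that the TIF4631 plasmid was kept. A culture that carried a plasmid without TIF4631 cannot be told apart from cells that hold the TIF4631 plasmid and do not raise its footprints: the TIF4631 ratio of -0.174 allows both, and URA3 at 884.3 CPM, near the 855 CPM of the control and unlike the 117.9 CPM beside raised TIF4631, goes with the control plasmid but rests on 1 library of each kind, and the marker of the TIF4631 plasmid is not given. A strain effect on TIF4631 remains open as a biological explanation and was not tested.

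The genes in opposite directions in the 2 strains were BIO5, with a difference of -8.11, BIO3 at -7.18, YJR154W at -6.25, BIO4 at -6.10, BIO2 at -5.18, VHT1 at -4.18, INO1 at -2.99 and YEL073C at -2.57. The median of the 5 biotin genes and INO1 was -2.104 in vps35 deletion and 3.421 in wild type, but a shared effect of TIF4631 could not be tested by these, because TIF4631 was not raised in the library labelled wild type with TIF4631. A later growth stage of the culture labelled wild type with TIF4631 may account for the wild-type side: ribosome biogenesis genes stood at -0.356 and Msn2/Msn4 targets at 0.526, both outside their random lists. These lists do not single out growth stage, and the labels' protocols give early log phase. The vps35 deletion side is also left open, where Msn2/Msn4 targets stood at 0.48 but ribosome biogenesis at 0.28. A different vitamin supply cannot be told apart from a later growth stage for the biotin genes, since no label records the medium of each culture. The 23 other genes past the rule of size, INO1 among them, do not settle this, since how each responds to vitamin supply was not examined. An interaction of strain and plasmid also remains open, untested with 1 library per group.

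List medians also went in opposite directions between the strains, each outside the central 95% of its random lists on both sides. The difference of medians, vps35 deletion minus wild type, was 0.63 for ribosome biogenesis, 0.37 for cytosolic ribosomal proteins and 0.27 for cell wall genes. It was -0.74 for phospholipid biosynthesis, -0.62 for galactose genes, -0.55 for the tricarboxylic acid and glyoxylate cycle and -0.23 for the respiratory chain. Between plasmids, the vps35 deletion contrast differed by 3.13 for CHA1, from -1.21 with the control plasmid to 1.92 with the TIF4631 plasmid. It differed by 0.63 for ribosome biogenesis and 0.37 for cytosolic ribosomal proteins. All of these differences rest on the library labelled wild type with TIF4631 and were not tested.

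A further pattern was the low level of 6 mitochondrially encoded ORFs in both deletion libraries, with a median log2 ratio of -2.411 under the control plasmid and -2.949 under the TIF4631 plasmid. Less of the whole mitochondrial compartment is argued against as the whole cause by the nuclear respiratory chain genes, at medians of -0.104 and -0.308, although the latter lay below its random lists and mitochondrial ribosomal proteins stood at -0.412 there. Loss of mitochondrial DNA from part of the cultures is argued against by the retrograde response genes CIT2, DLD3 and PDH1, which rise in cells without it and had medians of -0.141 and -0.587. No library known to lack mitochondrial DNA shows how far these genes respond in such cultures, so this argument is weak. A lower recovery of mitochondrial footprints in the deletion libraries cannot be told apart from an effect of the deletion, since library and strain are confounded. The 6 ratios ran from -3.18 to -1.83 under the control plasmid and from -4.76 to -1.44 under the TIF4631 plasmid, wider than the 0.5 set for one common factor. Between the deletion libraries, 1 of the 6 was higher with TIF4631, at 1.176, and 1 was lower by the rule of size. Counting error alone thus does not give the whole spread. These ORFs have few counts and each group 1 library, so a lower recovery stays open as part of the cause.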

How the results depend on the processing

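No paired analysis was possible because the labels give no replicate numbers, apart from the additive model, which compares libraries within strain and plasmid. With 1 library per group no replicate could be left out. The alternative that leaves the library labelled wild type with TIF4631 out of scaling and filtering was chosen after the data were seen. Without it, vps35 deletion under the control plasmid gave 13 higher and 25 lower ORFs, and TIF4631 in vps35 deletion 54 and 27. None of the 75 gene values and 42 list medians compared changed sign, which leaves out vps35 deletion under the TIF4631 plasmid and values near 0, but under total count scaling the interaction turned from more lower to more higher ORFs, 92 to 74. Of these gene values, over the alternatives, 432 stayed within their counting intervals and 3 moved, and of list medians 240 stayed and 12 moved, 10 of those under total count scaling. Scaling moved the median log2 ratio of all genes by at most 0.073. With no filter beyond 1 count, vps35 deletion under the control plasmid gave 24 higher and 47 lower ORFs, and TIF4631 in wild type 37 and 20. The extra ORFs have fewer than 200 counts over 4 libraries. With a filter of 1000 counts, which tests fewer ORFs, these contrasts gave 8 higher and 13 lower, and 3 lower. TIF4631 in vps35 deletion then gave 33 higher, and the interaction 52 higher and 59 lower. The correlation of TIF4631 ratios between strains was -0.048 with no filter. That of vps35 deletion ratios between plasmids was 0.299 with no filter and 0.377 at 1000 counts. In the additive model, vps35 deletion gave 83 ORFs with total count scaling, 47 with DESeq2 size factors, 52 without the 50 most abundant genes, 94 with no filter and 66 by the DESeq2 test. For TIF4631 it gave 2 with each of total count scaling, DESeq2 size factors, total counts without the 50 most abundant genes and the filter of 1000, 4 with no filter, and 6 by DESeq2. The cause of the changes with scaling and test was not tested. Counting error limits ORFs of low count: AI2, with 18 and 25 counts in the deletion libraries, has an interval of -3.98 to -2.51 under the control plasmid.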

Other observations

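The gene groups in the first 2 paragraphs were chosen after their values were seen, as were the tests in this part except that of coding length, and the groups are described without a test. In the vps35 deletion library with TIF4631, genes of glycine breakdown and one-carbon metabolism had a median log2 ratio of 1.39 to the deletion control, with 4 of 7 past the rule of size, GCV1 and GCV2 the highest, but SHM1 at -0.89 and ADE3 at -0.12 below 0. The same 7 genes had a median of -0.10 in the library labelled wild type with TIF4631, where TIF4631 was not raised. Pheromone response genes had a median of 0.67 in vps35 deletion with TIF4631, with 2 of 6 past the rule, among them AGA1 at 2.08 and SST2 at 1.32, although FAR1 lay at -0.39.

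Genes that respond to zinc had a median of -0.74 in vps35 deletion under the control plasmid, with 6 of 6 below 0 and ZRT1 at -2.53 and the regulator ZAP1 at -1.12 past the rule of size. Cell wall integrity genes had a median of 0.83 there, with 8 of 8 above 0, from 0.20 to 1.31. The deletion under the TIF4631 plasmid showed medians of -1.73 and 1.22 for these groups, against the library labelled wild type with TIF4631. That library itself had medians of 0.70 and -0.20 for these groups against the wild-type control, so the larger values draw partly on it. ARO10, which acts in the breakdown of aromatic amino acids, stood at 0.91 and 1.81 in the vps35 deletion contrasts under the control and TIF4631 plasmids.

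The low URA3 count in the vps35 deletion library with TIF4631 may come from reduced expression of the pyrimidine genes under the activator Ppr1. The test argues against this: URA1 at 0.72 and URA4 at 0.37 had a mean log2 ratio of 0.546 to the deletion control, where the hypothesis needed a decrease. The uracil permease FUR4 stood at 0.90. Whether the TIF4631 plasmid differed in its marker or copy number was not tested.

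A second hypothesis, that raised eIF4G changes ribosome occupancy by ORF length, was given a bound before its result was seen. Across 4996 genes, which are not independent replicates, the Spearman rho of coding length and the TIF4631 log2 ratio in vps35 deletion was 0.030. This was below the bound of 0.1 in size, which argues against a relation of that size between length and footprint level in these libraries. Footprint level holds mRNA level and translation together, so occupancy per mRNA was not tested. The same rho was -0.028 for the library labelled wild type with TIF4631.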
